A study of Homo sapiens with 24 samples.

How the data were processed

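Estrogen receptor alpha (ER) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF7, an estrogen receptor positive human breast cancer cell line. Per the labels, unsynchronized cultures in full estrogenic medium received vehicle (DMSO), 500 nM everolimus (RAD001) or 500 nM vistusertib (AZD2014) over 2 hours, and were fixed with formaldehyde, sonicated and immunoprecipitated with a polyclonal antibody against the receptor. The control samples are called vehicle in their titles and in the treatment protocol, while other label fields call the same samples untreated; they were taken as vehicle. The 24 samples form 6 groups of 4, an ER ChIP group and an input group per treatment, and each group spans passages 19 to 22.

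Per the submitters' processing notes, Bowtie2 2.2.6, MACS2 2.0.10.20131216 and DiffBind were used on build hg38/GRCh38. The notes give no settings, no DiffBind version and no account of how DiffBind was used. The deposited data are 3 peak lists, 1 per treatment. The labels tie the 4 ChIP samples of a treatment to the same list, and how the replicates were combined is not given in the sources used here. There is therefore no replicate spread for any peak, no p-value was computed across peaks, and the input samples enter only through the background that the authors' caller used.

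Each deposited peak has a start, an end, a summit and the authors' values for it. The fold enrichment is the authors' ratio of ChIP signal to the local background at the summit. The significance is the authors' −log10 p and −log10 q from their peak caller. The deposited score equals 10 times the −log10 q, rounded down to a whole number, for 100% of vehicle and everolimus peaks and all but a few vistusertib peaks. The lowest −log10 q was 3.08 in the vehicle list, 3.06 in the everolimus list and 3.06 in the vistusertib list, and the shortest peak was 200 bp in each. The authors' fold, score and −log10 values were used to describe, rank or filter peaks within their own list and to recover the caller's background, which was compared between lists as a measure of depth, together with the number of peaks with −log10 p of at least 30. No region's strength was compared between lists.

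The number of reads per library is not given in these lists. For most peaks the caller's pileup and background at the summit could be recovered from the deposited fold and −log10 p, as the pair of values that gives both: a whole pileup fitted 95.7% of vehicle peaks and 96.3% of everolimus peaks, with a tolerance of 0.001. In the vistusertib list 96.4% of peaks had a fitting pair when the pileup need not be whole, a looser condition. A pileup scale of 0.935 was then inferred from peaks at the most frequent background. This looser recovery was not tested on simulated data. The most frequent background, which scales with the number of reads and their fragment length, was 6.72 in the vehicle list, 7.12 in the everolimus list and 7.04 in the vistusertib list. With the scaling of the vistusertib pileup undone, its ChIP background was 7.53. Intervals on counts and shares are 95% Wilson intervals, and beside a count of 0 the share that 3 peaks of the total would give is also stated. Both cover counting error only, not the variation between cultures or immunoprecipitations.

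A peak counted as shared when a peak of the other list overlapped it by at least 1 bp. Overlapping peaks of the 3 lists were merged into regions. As both drugs are compared with 1 vehicle list, unchanged lists were simulated: 300000 sites with 1 common strength each, read by 3 lists with independent noise of equal size, each list taking its observed number of regions from the top. The noise was fitted to the observed pairwise sharing, and 20 simulations were drawn for each of 2 shapes of the site strengths, exponential and normal.

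Gene positions came from a RefSeq table of assembly GRCh38.p14, the build of the lists, with 1 start and 1 end per gene and no strand, exons or genome sequence. The share at promoters was therefore replaced by the share of summits within 1 kb of either end of a protein-coding gene, on chromosomes 1 to 22 and X. The share of peaks with an estrogen response element, planned for the same classes, needs the genome sequence and is not reported here. Location shares were set beside 10000 random sets of peaks of the same list, matched on decile of the fold. The first form of these sets drew from shared peaks alone and was replaced, after its values had been seen, because it was too narrow on simulated data; the directions were the same with both.

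The 11 gene lists cover estrogen response, the mTOR-PI3K pathway, receptor tyrosine kinase feedback, cell cycle, sterol and lipid synthesis, ribosomal proteins, luminal transcription factors and ER cofactors, apoptosis, and markers of basal epithelium, liver and neurons. They were written from general knowledge before the data were examined, as were the comparisons, the overlap rule, the rule for named peaks and the alternatives called planned. A member counted when an unshared peak had its summit within 50 kb of the gene body, in place of the transcription start. The number of members was set beside 10000 random draws of as many protein-coding genes, from classes with a similar number of merged regions nearby. These draws are called random lists with as many regions below. Genes were drawn independently, so the draws do not reproduce neighboring members that share a peak. The random draws of peaks, for location and for counts of peaks near a list, likewise treat peaks as independent. Named peaks are, for each drug against vehicle and in each direction, the 10 unshared peaks of highest fold within their list, each with its nearest protein-coding gene, 5 in each direction between the drugs, and the 5 of highest fold common to the 3 lists. The rule also names list members within 50 kb of an unshared peak from the highest of 4 equal bins of its list by fold, and no member met it.

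The calculations were tested on simulated data. All seeded removals and additions of peaks to the vehicle list (35517 peaks) were found, 100% of each. When vehicle peaks were dropped at random within deciles, 6.00% of 200 draws fell outside the central 95% of the matched location sets, and 100% did when peaks at gene ends were dropped 1.5 times as often. For the peak counts near a gene list matched on decile of the fold, added after the data were seen, a seeded loss at 0.7 times the rate among the 496 vehicle peaks near estrogen response genes was found in 85.5% of 200 draws. In these tests peaks were dropped independently at set rates per decile. Unshared peaks in the data clustered along the genome, so the power and the error rates may differ there. The power of the planned member counts was not simulated. Random lists of 50 genes, judged by percentile, fell outside the central 95% in 5.25% of 400 draws. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered stricter peak thresholds, other overlap rules, lists of equal length, only the stronger peaks, other distances to genes and other matching.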

Results

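ER ChIP-seq peaks were compared between MCF7 cells given vehicle, everolimus or vistusertib for 2 hours. Everolimus is a rapamycin analogue that inhibits mTOR, a growth-controlling kinase, as part of mTOR complex 1, and vistusertib is an ATP-competitive inhibitor of the mTOR kinase itself. The comparisons address how ER binding in estrogen-containing medium differs after short mTOR inhibition. The vehicle list held 35517 peaks, the everolimus list 42699 and the vistusertib list 29720. The everolimus list was 1.20 times and the vistusertib list 0.837 times as long as the vehicle list. Each treatment has 4 ChIP samples and 1 list, so there is 1 value per treatment, no replicate spread and no test of a difference between treatments. Positions are on build hg38, and "no peak" means that no peak passed the authors' caller there.

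The strongest binding sites were common to the 3 treatments. The 5 common peaks of highest fold in the vehicle list lay in RNF223 (chromosome 1, 1073295 to 1074595, 51.9-fold over background), in CAMTA1, a calmodulin-binding transcription activator (chromosome 1, 7447649 to 7448339, 51.7-fold), 115168 bp from the cation channel gene TRPC6 (chromosome 11, 101336003 to 101336807, 51.3-fold), in GNG7, a G protein subunit (chromosome 19, 2524791 to 2525548, 50.9-fold), and 33714 bp from the glucose transporter gene SLC2A1 (chromosome 1, 42992235 to 42992906, 50.6-fold). Of the 62 estrogen response genes matched, 58 had a region with a peak in all 3 lists within 50 kb, as did 29 of the 32 luminal transcription factors and ER cofactors. Most members of other lists also had one, such as 37 of 52 ribosomal protein genes and 19 of 26 liver markers. The median number of regions per gene was 10 for estrogen response genes, against 2.5 and 2 for these. The classical targets named next were chosen after their values were seen. TFF1, a secreted trefoil peptide, had 14 merged regions within 50 kb, 9 of them in all 3 lists. GREB1, an ER cofactor induced by estrogen, had 24 regions with 17 in all lists, XBP1 had 9 with 7, PGR, the progesterone receptor gene, had 10 with 4, and the pioneer factor gene FOXA1 had 15 with 12. The gene of the receptor itself, ESR1, had 26 regions, of which 17 were in all lists.

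The lists were close to nested. Of 46443 merged regions, 26063 (56.1%) had a peak in all 3 lists. A further 8696 were in the everolimus list alone and 6061 in the vehicle and everolimus lists. In contrast 2409 were in the vehicle list alone, 1767 in both drug lists but not in the vehicle list, 873 in the vistusertib list alone and 574 in the vehicle and vistusertib lists.

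**Figure D1:**
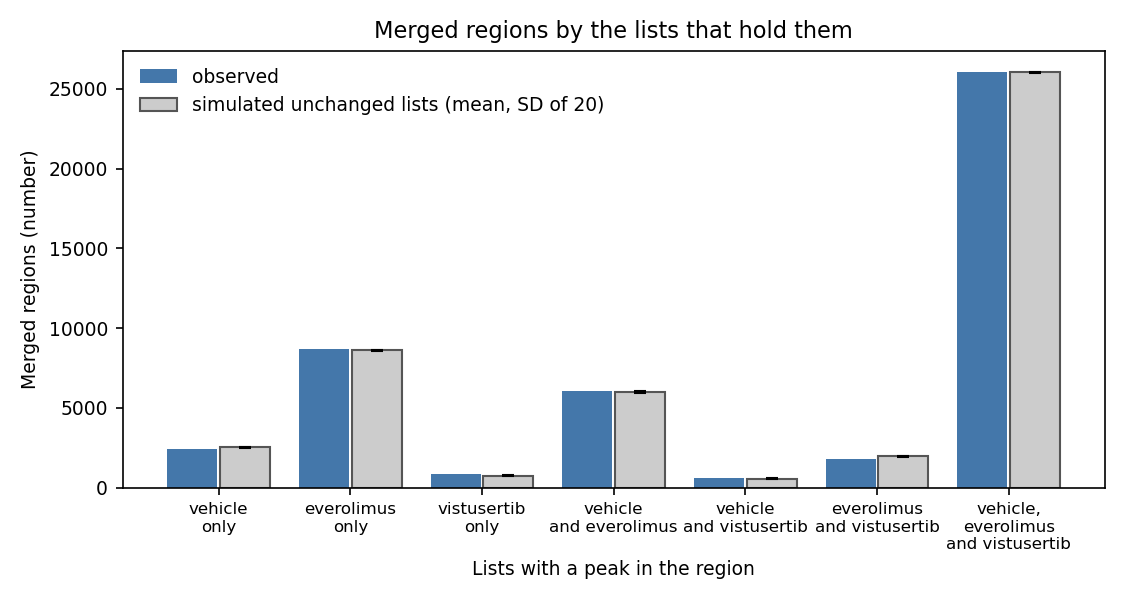
Number of merged regions (y axis) by which of the 3 lists had a peak there (x axis), observed and in 20 simulations of unchanged lists (grey bars, mean; error bars, SD). Regions in all 3 lists (26063) and in the everolimus list alone (8696) are the most frequent, and the simulated means, with exponential site strengths, are 26026 and 8611. The noise and lengths of the simulated lists were fitted to the observed lists.

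Most vehicle sites were also called under everolimus, whose longer list held further weak sites. Of the 35517 vehicle peaks, 2995 (8.43%, interval 8.15 to 8.73) had no everolimus peak, while 10478 of 42699 everolimus peaks (24.5%, interval 24.1 to 24.9) had no vehicle peak. With the 29720 most significant peaks of each list, which makes both directions nearly equal by construction, 3964 (13.3%) and 4198 (14.1%) had no partner. The unshared peaks were the weak ones of their lists. With each list parted into 4 equal bins by fold, 55.6% of everolimus peaks in the lowest bin had no vehicle partner, and 0.0281% (3 of 10674) in the highest. Of the vehicle peaks 24.4% in the lowest bin and 0 of 8879 in the highest had no everolimus partner, which allows a share of up to 0.0338% as 3 peaks of the total (Wilson upper limit 0.0432%).

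The everolimus peaks of highest fold without a vehicle peak ranged from 9.61-fold to 11.5-fold, and 7 of the 10 lay over 100 kb from a protein-coding gene. The highest was inside COBLL1 (chromosome 2, 164693419 to 164693750, 11.5-fold), with a vehicle peak 491 bp and a vistusertib peak 535 bp away. Others lay inside EXT2, a heparan sulfate polymerase (chromosome 11, 44192527 to 44192832, 9.73-fold), and 11348 bp from DOCK5, an exchange factor for a Rho-family GTPase (chromosome 8, 25173180 to 25173473, 9.86-fold). The remaining 7 were nearest to SLC22A23, ANKRD50, AKR1E2, CDH8, CCDC54, IFTAP and ELAC2. In 4 of these 10 the vistusertib list had an overlapping peak, and in 6 a vehicle peak lay within 5 kb.

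The vehicle peaks of highest fold without an everolimus peak ranged from 7.12-fold to 8.71-fold, between the percentiles 57.5 and 67.4 of the vehicle list. They lay inside AGPAT3, an acyltransferase of phospholipid synthesis (chromosome 21, 43879866 to 43880266, 8.71-fold), inside PELP1, an ER coregulator (chromosome 17, 4680855 to 4681151, 7.77-fold), inside the kinase gene HUNK (chromosome 21, 31987282 to 31987574, 7.66-fold), and inside or near LOC124900866, PPFIA2, NWD1, RSU1, ECE1, IGSF22 and the keratin gene KRT15. Of the 10, 7 were overlapped by a vistusertib peak, and 7 had an everolimus peak within 5 kb. The peak in HUNK lay 105 bp from one.

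Many weak vehicle sites were not in the shorter vistusertib list. Of the vehicle peaks, 8569 (24.1%, interval 23.7 to 24.6) had no vistusertib peak, and 2679 of 29720 vistusertib peaks (9.01%, interval 8.69 to 9.35) had no vehicle peak. With lists of equal length, where the directions are again nearly equal by construction, the counts were 4783 (16.1%) and 4665 (15.7%). The share of vehicle peaks without a vistusertib partner was 54.2% in the lowest of the 4 bins by fold, 34.9% and 7.32% in the next bins, and 0.0450% (4 of 8879) in the highest. No vistusertib peak of the highest bin lacked a vehicle partner (0 of 7430, which allows a share of up to 0.0404% as 3 peaks of the total; Wilson upper limit 0.0517%).

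The strongest vehicle peak without a vistusertib peak lay 625568 bp from MAN1A1, a mannosidase of the Golgi (chromosome 6, 119975991 to 119976338, 14.6-fold, percentile 84.5 of the vehicle list), with a vistusertib peak 1121 bp away. It was followed by a peak 21499 bp from AADAC, an esterase gene (chromosome 3, 151792441 to 151792814, 12.2-fold), 63452 bp from the nearest vistusertib peak, and by one 674719 bp from the semaphorin gene SEMA3D (chromosome 7, 85924767 to 85925110, 10.9-fold). Peaks inside WNT7B, a Wnt ligand (chromosome 22, 45934120 to 45934430), inside MGAT3, a glycosyltransferase (chromosome 22, 39469960 to 39470319, 10.1-fold; 301 bp from a vistusertib peak), and nearest to PKIA, RAPGEF2, EFNA5, HS3ST5 and TBPL1 completed the 10. All 10 were overlapped by an everolimus peak.

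The vistusertib peaks of highest fold without a vehicle peak ranged from 6.87-fold to 7.74-fold. The highest lay 627107 bp from GATA3, a luminal transcription factor (chromosome 10, 8702134 to 8702475, 7.74-fold) and 169 bp from a vehicle peak, and the next 325161 bp from the hyaluronan synthase gene HAS2 (chromosome 8, 121966442 to 121966760, 7.35-fold) and 326 bp from a vehicle peak. The others were in or nearest to CITED4, a transcriptional coactivator gene, ANKRD44, C4orf36, FAM193A, NUDT12 (134049 bp away), GGTLC1 (218483 bp away), BLTP3A and ROBO3. An everolimus peak overlapped 8 of these 10, all but those near HAS2 and ROBO3, and the peak near HAS2 lay 278 bp from an everolimus peak.

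**Figure D2:**
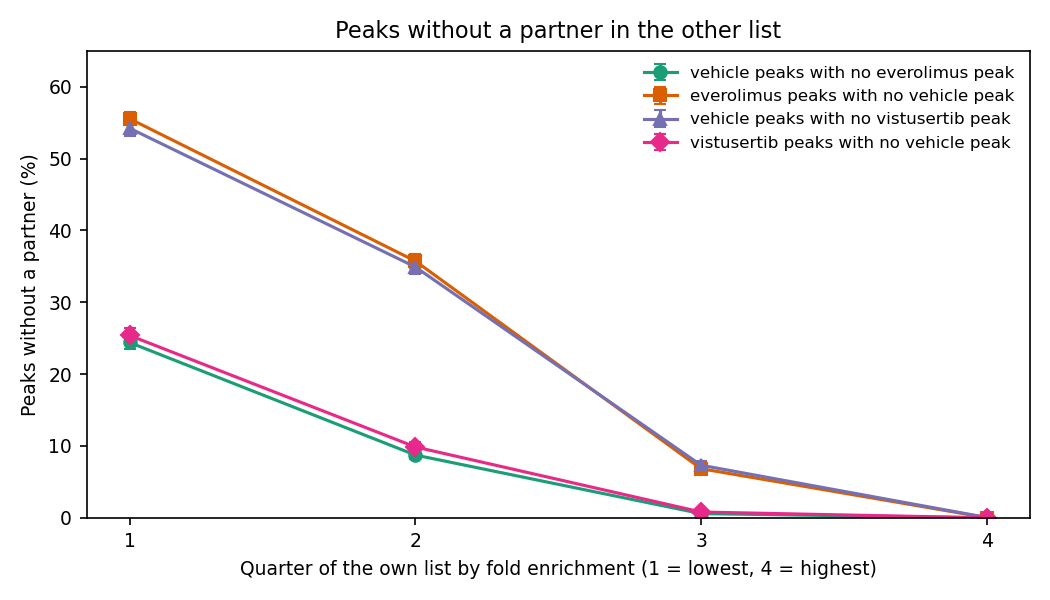
Percent of peaks without an overlapping peak in the other list (y axis) for 4 equal bins of the own list by the authors' fold enrichment (x axis), for vehicle against each drug in both directions; error bars are 95% Wilson intervals. Each curve falls from the lowest bin to the highest, where at most 0.0450% of peaks lack a partner.

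The drugs, which differ in how they inhibit mTOR, were compared at the same dose and time. The everolimus list covered nearly all vistusertib peaks: 1452 of 29720 (4.89%, interval 4.65 to 5.14) had no everolimus peak. In the other direction 14790 of 42699 everolimus peaks (34.6%, interval 34.2 to 35.1) had no vistusertib peak, including 67 in the highest bin by fold (0.628%). The strongest of these lay 134223 bp from the protocadherin gene PCDH18 (chromosome 4, 137384500 to 137384890, 12.8-fold) and 117536 bp from PKIA, a protein kinase A inhibitor (chromosome 8, 78398657 to 78398983, 12.8-fold). The next lay 140707 bp from RBMS3, 277541 bp from TBL1XR1, a corepressor subunit, and 1651299 bp from SPRY2, a feedback inhibitor of receptor tyrosine kinase signaling. Each of the 5 overlapped a vehicle peak. The strongest vistusertib peaks without an everolimus peak were those near HAS2 and ROBO3 and peaks inside TNFRSF11A, SH3D21 and MTHFD1L, from 6.49-fold to 7.35-fold, and 1 of the 5 overlapped a vehicle peak. The peak near HAS2 lay 278 bp from an everolimus peak. With lists of equal length 4974 (16.7%) everolimus peaks and 4598 (15.5%) vistusertib peaks lacked a partner.

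Both drug comparisons use the same vehicle list, so regions can change together by chance. The 2409 regions in the vehicle list alone compare with 2518 (SD 42.4) in unchanged lists simulated with exponential site strengths and 2408 (SD 41.4) with normal ones, and with 720 if the drugs lost vehicle regions independently or 1485 if they did so within deciles of vehicle fold. The 1767 regions in both drug lists without a vehicle peak compare with 1952 (SD 36.3) and 2121 (SD 40.2) simulated. A value of 595 for independent lists was taken over all 46443 merged regions. As regions with a vehicle peak cannot be gained, that value is too low to serve as a reference. The unchanged lists that share 1 vehicle list thus held about as many such regions as observed, or more. Their noise and lengths were fitted to these same lists, however, so a real change would partly be taken as noise. The likeness therefore cannot show that the drugs shared no change.

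Peaks in different classes lay in different parts of the genome. Of all vehicle peaks 6.39% had their summit within 1 kb of a gene end, 49.4% lay inside a gene body and 24.5% were over 50 kb from any protein-coding gene. Weak peaks lay at gene ends more often, so the comparison depends on matching: everolimus peaks with no vehicle peak were at gene ends in 8.01% (interval 7.51 to 8.55), above the 6.01% of everolimus peaks shared with vehicle, but below the 9.10% of random everolimus peaks of the same fold (central 95% of the sets 8.72 to 9.47), and 27.6% were over 50 kb from a gene against 23.8% of random peaks. Vehicle peaks with no vistusertib peak were similar, with 6.70% at gene ends against 8.05% and 26.6% over 50 kb from a gene against 22.7%. In the opposite direction, 10.6% of vehicle peaks with no everolimus peak (8.80% of random peaks) and 13.6% of vistusertib peaks with no vehicle peak (10.4% of random peaks, central 95% of the sets 9.42 to 11.4) lay at gene ends. Between the drugs, 15.5% of vistusertib peaks lacking an everolimus partner lay at gene ends against 10.9% of random peaks, and 6.51% of everolimus peaks lacking a vistusertib partner against 8.57%. By chromosome, the everolimus list was longest relative to vehicle on chromosome 4 (1.32 times) and shortest on the gene-dense chromosome 19 (1.07 times).

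**Figure D3:**
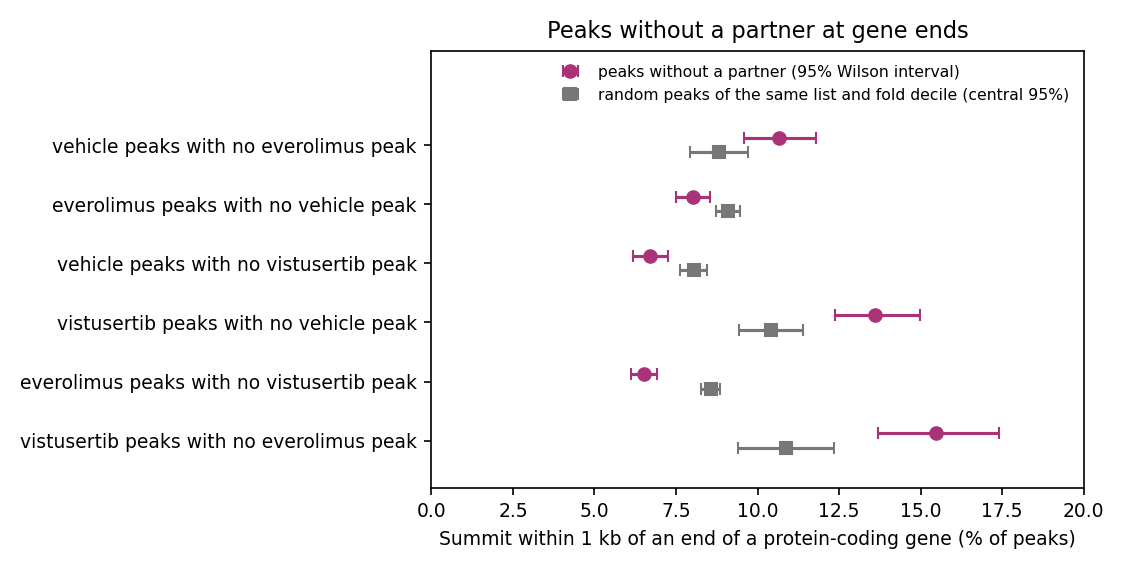
Percent of peaks with the summit within 1 kb of an end of a protein-coding gene (x axis) for each class of peaks without a partner (y axis; circles, 95% Wilson interval), beside random peaks of the same list and decile of fold (squares, central 95% of 10000 sets). Vistusertib peaks without a vehicle partner (13.6%) lie above their random peaks, and everolimus peaks without a vehicle partner (8.01%) lie below theirs.

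Among the gene lists, 2 of the 66 counts over 11 lists and 6 directions lay outside the central 95% of matched random gene lists. Chance would give up to 3.30, and fewer where counts at a bound are taken as inside, as here. Of the estrogen response genes, 40 of 62 had a vehicle peak with no vistusertib peak nearby, against 47.0 for random lists with as many regions (percentile 1.08). In the other directions the list stayed within the range, with 24 against 30.9 for vehicle peaks with no everolimus peak (percentile 3.11), 19 against 26.2 for vistusertib peaks with no vehicle peak, at the lower bound of 19 to 33 (percentile 2.51), and 50 against 48.1 for everolimus peaks with no vehicle peak. With peaks matched on −log10 q, an alternative added after the data were seen, the estrogen response list held 81 vehicle peaks with no vistusertib peak against an expected 90.3, inside the central 95% of 77 to 103; matched on decile of the fold 95.7 were expected, with the 81 just below the range of 82 to 110. Apoptosis genes had more vistusertib peaks with no vehicle peak, in 12 of 26 members against 6.16 (percentile 99.5). These members, listed after their values were seen, are the BCL2 family genes BCL2, BCL2L1, MCL1, BID, BIK, BBC3, PMAIP1, BMF and HRK, the caspase regulator genes CFLAR and BIRC5, and TNFRSF10B, a death receptor gene. The list holds both inhibitors and promoters of cell death.

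With as many regions matched, the other lists stayed inside the range in the 6 directions, where a count at a bound was taken as inside. Basal markers were at the upper bound of 11 to 18 for everolimus peaks with no vistusertib peak, with 18 of 22 against 14.3 (percentile 97.6). MAPKAP1, INPP4B, IGF1R and ERBB4 are named here after their values were seen. In the mTOR-PI3K pathway list, 31 of 51 members had an everolimus peak with no vehicle peak (29.4 in random lists) and 28 a vehicle peak with no vistusertib peak (26.9). Matched on −log10 q instead, 46 of the 226 vehicle peaks near these genes had no vistusertib peak where 58.5 were expected (central 95% 48 to 69). MAPKAP1, a subunit of mTOR complex 2, had 26 regions with 17 in all lists, and INPP4B, a phosphoinositide phosphatase, had 22 with 9. Receptor tyrosine kinase genes had an everolimus peak with no vehicle peak in 22 of 29 (19.7), and a vehicle peak with no vistusertib peak in 21 (18.5). The growth factor receptor gene IGF1R had 45 regions, 28 in all lists, and the large ERBB4 gene had 32 with 11 in all lists, with 14 everolimus peaks that had no vehicle peak. For everolimus peaks with no vehicle peak, counts were 25 of 46 cell cycle genes (21.8; by peaks matched on −log10 q, 36 of 166 against 47.2), 16 of 30 sterol and lipid synthesis genes (16.6), 27 of 52 ribosomal protein genes (25.4) and 27 of 32 luminal factors (23.04). For vehicle peaks with no vistusertib peak they were 22 (19.5), 13 (14.9), 25 (22.02) and 23 (22.3). Marker genes of basal epithelium, liver and neurons had everolimus peaks with no vehicle peak in 15 of 22 (12.5), 9 of 26 (12.1) and 7 of 22 (8.41). Vehicle peaks with no vistusertib peak lay near 14 basal genes (11.2) and 7 neuron genes (7.27), and near 12 liver genes, at percentile 79.0 of random lists.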

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

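The restriction to peaks with −log10 q of at least 20 in their own list, the distance of 1 kb and the matching on strength or chromosome were chosen after the data were seen; the other alternatives were planned. The 6 differences between peaks without a partner and random peaks at gene ends kept their direction and stayed outside the central 95% in all 36 alternatives run. Of 66 alternative counts of unshared peaks and regions, 45 stayed within 1.5 times the reported count, under −log10 q thresholds of 5 and 10, standard chromosomes, merging within 500 bp and no peak within 1 kb among others. Unshared counts were smallest when only strong peaks were kept. In the upper 50% of the own list by fold, vehicle peaks with no everolimus peak numbered 52, the reverse 733, vehicle peaks with no vistusertib peak 654, the reverse 60, everolimus peaks with no vistusertib peak 2002 and the reverse 14; 28 regions were in the vehicle list alone and 26 in both drug lists without vehicle. With −log10 q of at least 20 in the own list the same 6 pairwise counts were 162, 1413, 1383, 132, 3395 and 44. Lists of equal length removed the order of the lists by construction: everolimus peaks with no vehicle peak numbered 4198, vehicle peaks with no vistusertib peak 4783, the reverse 4665, everolimus peaks with no vistusertib peak 4974 and the reverse 4598. Vistusertib peaks with no everolimus peak numbered 2819 under reciprocal overlap of 50% and 2476 with summits within 100 bp, which ask for more overlap.

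Counts of gene lists outside the random range changed with the reach, the length of the lists and the kind of count, from 0 to 6 lists per direction. They became 1 for vehicle peaks with no everolimus peak within 100 kb, and, with lists of equal length, 2 for vehicle peaks with no vistusertib peak and 1 for vistusertib peaks with no everolimus peak. With peaks counted in place of members, against random peaks of the same list in place of random genes, and matched on decile of the fold, they were 1 and 3 for vehicle against everolimus in the 2 directions, 2 and 3 for vehicle against vistusertib and 6 for everolimus peaks with no vistusertib peak; matched on 100 bins of −log10 q they were 1, 2 and 6 for vehicle peaks with no everolimus peak, the reverse, and everolimus peaks with no vistusertib peak. With that matching the mTOR-PI3K list for vehicle peaks with no vistusertib peak and the apoptosis list for the reverse were also outside. The peak counts left the range more often than the planned member counts, but their draws treat peaks as independent. The cause was not tested. The 2 lists outside the random range (in brackets) stayed outside at 10 kb, 100 kb and equal list length. Estrogen response genes with a vehicle peak lacking a vistusertib partner numbered 27 (30 to 43), 44 (48 to 57) and 25 (27 to 41). Apoptosis genes with a vistusertib peak lacking a vehicle partner numbered 8 (1 to 7), 16 (5 to 14) and 17 (5 to 14). By peaks matched on −log10 q, the estrogen response count of 81 was inside 77 to 103. The apoptosis count of 16 was above 5 to 15. The 5 alternatives planned for the estrogen response element were not run, as they need the genome sequence. No paired analysis was possible because each treatment has 1 list and its peaks carry no replicate, and for the same reason no replicate could be left out. The depth of each library is unknown, and a region without a peak may hold binding below the caller's threshold, which the lists cannot show. Of the 10478 everolimus peaks without a vehicle peak, 9253 had none within 1 kb, a count that bears on shifted peaks only.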

Other observations

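The tests of the vistusertib background, of simulated unchanged lists and of sterol genes, and the matchings on peak strength, were chosen after the results were seen, and the windows and genes named here were picked from the same data. Genes of sterol and lipid synthesis had vehicle peaks that overlapped no peak of either drug. Within 50 kb of the 30 genes lay 89 vehicle peaks, of which 14 had neither an everolimus nor a vistusertib peak, the highest percentile among the 11 lists. They were weak peaks, from 2.62-fold to 5.16-fold. MVD, an enzyme of the mevalonate pathway, had 4 of them, including a peak 8190 bp from the gene (chromosome 16, 88643600 to 88643895, 5.16-fold). LDLR, the low-density lipoprotein receptor gene, had 3, one inside the gene (chromosome 19, 11129801 to 11130018, 3.66-fold). INSIG1, a regulator of sterol sensing, had 2, one inside the gene (chromosome 7, 155300906 to 155301210, 3.56-fold), and DHCR24, FDPS, DHCR7, FASN and the neighbors FADS1 and FADS2 shared the rest. In the opposite direction, apoptosis genes had 11 everolimus peaks shared with vistusertib and not with vehicle, against 4.20 expected from peak strength (central 95% 1 to 8). This list had already stood out for its vistusertib peaks with no vehicle peak, so the count is not separate support. All everolimus peaks with no vehicle peak near these genes numbered 28 against 27.95 expected. Ribosomal protein genes had 14 shared drug peaks against 7.83, at the upper bound of 3 to 14. Location, single genes and peaks within 1 kb were not checked in this direction.

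The planned test found no excess at sterol genes: 10 of 30 had a vehicle peak with no everolimus peak, against 8.36 for random genes with as many regions (percentile 76.2). The pattern was found by looking through 66 counts under 3 matchings and then through both-drug counts of 11 lists. Matched on 100 bins of −log10 q, 16 peaks lacked an everolimus peak against 6.83 expected, but 21 lacked a vistusertib peak against 19.9, within the range; for both drugs together 5.46 peaks were expected against the 14 (central 95% 2 to 10), 5.57 with location also matched, and without MVD 4.99 against 10 (central 95% 2 to 9). Several of the 14 lay next to a drug peak, such as LDLR peaks 215 bp and 464 bp and an MVD peak 244 bp from a vistusertib peak, and with any drug peak within 1 kb taken as a partner 9 were left against 4.58 expected (central 95% 1 to 9, percentile 98.0), or 6 against 4.23 without MVD. Shifted or split peaks may thus account for part of the excess, what is left lies at the bound of the range, and no biological explanation was tested. These ranges treat peaks as independent, while unshared peaks clustered along the genome (below) and many of the 14 lay near few genes. The ranges may therefore be too narrow.

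The lengths of the lists did not follow the recovered background, a measure of read depth. The recovered background of the vistusertib list was 1.05 times that of the vehicle list, with an inferred scaling of its ChIP by 0.935. Without that scaling its ChIP background was 1.12 times the vehicle value, above the 1.06 times of everolimus. As the vistusertib list held fewer peaks than the vehicle list, this argues against a lower depth unless fragment lengths differed. Everolimus peaks with −log10 p of at least 30, thinned to the vehicle background, were still 1.15 times as many as in the vehicle list, against 1.19 times before thinning; a first thinning test at the caller's own threshold was void and was replaced. A single ranking of sites read to a different depth by each list, with equal noise, gave classes of similar size but not the same. With exponential site strengths the farthest by ratio, regions in the vistusertib list alone, was 1.19 times its simulated number (873 against 734, SD 28.3). With normal ones, 1767 regions were in both drug lists without vehicle against 2121 (SD 40.2). With lists of equal length and exponential strengths, 2450 regions were shared by vehicle and everolimus alone against 2020 (SD 36.4). In the same simulation 2930 were in the vistusertib list alone against 2442 (SD 40.9). These differences exceed the SD of the simulations, which covers the random draws only and not the fit or the shape of the site strengths. The shape alone moved the regions in the vehicle and everolimus lists from 5998 (exponential) to 6276 (normal). By the rule set for this test, the ratio of 1.19 was too small to decide on such a ranking with equal noise. A ranking with unequal noise was not simulated and stays open. A common ranking would arise from unequal immunoprecipitation efficiency as well as from a treatment effect that scales binding at every site alike, and the lists cannot separate these.

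The contrast in location also has technical candidates. Peak strength did not account for it: matched on 100 bins of −log10 q, 9.22% of everolimus peaks would lie at gene ends against 8.01% of those without a vehicle partner, and 11.1% of vistusertib peaks against 13.6%. Gene density of chromosomes did not either, with 8.92% and 10.7% when matched on chromosome and decile of fold. A difference between libraries in the recovery of GC-rich or open chromatin may also produce it and was not tested, since no genome sequence was used here; a treatment effect on distal sites remains equally open.

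Unshared peaks were unevenly spread along the genome at a given fold. The variance of everolimus peaks with no vehicle peak over 2757 windows of 1 Mb was 2.52 times that of independent draws (central 95% of 100 draws 0.943 to 1.07) when matched on decile of the fold, and 1.53 times when matched on 100 bins of −log10 q. For vehicle peaks with no vistusertib peak these ratios were 1.91 and 1.23. Windows with the fewest unshared peaks for their fold lay on chromosomes 17, 20 and 3, in parts of the genome where the recovered background was high. At 47000001 to 48000000 on chromosome 20 the median background under everolimus peaks was 111, and at 61000001 to 62000000 on chromosome 17 it was 139, against 10.6 over the whole list. In the latter window 5 of 41 everolimus peaks had no vehicle peak, where 22.9 were expected from the fold and 9.65 from −log10 q. Segments of chromosomes 17 and 20 are known to be amplified in MCF7, and fold enrichment ranks peaks in such regions lower than their significance does.

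Matched on −log10 q, everolimus peaks with no vistusertib peak were fewer than expected near 6 of the 11 lists: 146 against 161 for estrogen response, 74 against 91.6 for the mTOR-PI3K pathway, 50 against 64.9 for cell cycle, 53 against 69.0 for ribosomal proteins, 28 against 37.8 for apoptosis and 13 against 19.4 for neuron markers. By members matched on the number of regions, the planned count, none of these lists left the range: 54 against 52.9, 33 against 33.4, 29 against 25.4, 31 against 29.7, 14 against 16.2 and 8 against 9.93, in the same order. The numbers expected by peaks treat peaks as independent, while unshared peaks clustered along the genome in the pairs examined above, so their ranges may be too narrow. Everolimus peaks with no vistusertib peak were also farther from genes in general, 29.0% over 50 kb from any gene against 24.1% of random peaks of the same fold. Everolimus peaks with no vehicle peak were fewer near cell cycle genes, 36 against 47.2 (central 95% 39 to 56), and near luminal factors, 56 against 67.03 (57 to 78), although by members these lists lay above the mean of random lists, at percentiles 87.8 and 97.1.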
